A study of Homo sapiens with 10 samples.

How the data were processed

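Bulk RNA-seq was measured in 10 libraries of sensory neurons differentiated from RUES2, an established human embryonic stem cell line, in which a tdTomato fluorescent reporter had been placed at AVIL, the gene of the actin-binding protein advillin. The cultures followed 1 of 3 differentiation protocols, meant to bias neurons toward a nociceptor, a low-threshold mechanoreceptor or a proprioceptor phenotype, and were taken at day 60 in vitro. The labels gave 4 libraries to the nociceptor protocol, 3 to the mechanoreceptor protocol and 3 to the proprioceptor protocol, and each library was assigned to its group from its title. The titles called the libraries biological replicates and did not say whether these were separate differentiations, so the p-values measure the spread between these libraries, which may in part be technical. The labels did not say whether cells were sorted for the reporter before extraction.

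Per the labels' protocols, RNA was extracted with Trizol, its integrity was assessed on a Bioanalyzer, cDNA was made with the Clontech Ultra Low v4 kit, which primes on poly(A) tails and amplifies the full-length cDNA, libraries were made with NexteraXT, and the multiplexed libraries were sequenced as paired 75 nt reads. Per the submitters' processing notes, reads were quantified with kallisto 0.50.1 on GRCh38.p14. The authors deposited estimated counts per transcript and per gene, rounded to whole numbers, and TPM values (transcript abundance corrected for length and scaled to the same sum in each library) per transcript and per gene. How transcripts were summed to gene symbols was not given in the sources used here. Pseudoalignment divides reads that fit several transcripts by estimation, so genes with near-identical copies, and transcripts of 1 gene that overlap over most of their length, carry an estimation error that the deposited values do not show. The kit does not mark strand, so reads of overlapping antisense genes cannot be told apart.

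The gene tables held 30358 entries, of which 1 had a blank name. That entry took between 0.733% and 1.66% of the counts and between 2.81% and 8.80% of the TPM of a library, and it was left out of library sizes and tests, which leaves 30357 named genes with no repeated names. The named genes held between 27891186 and 44541262 counts per library, so counting error was small beside the spread between libraries for all but the lowest genes, and library preparation by PCR means that counts are not independent molecules. Replicates were checked for duplicates with a chi-square test of their counts. The lowest value within a protocol was 141.7 per degree of freedom, so no library was counted as a copy of another. Transcripts were given gene names through the Ensembl transcript identifier in a GENCODE annotation of GRCh38. Of 207133 transcripts, 151077 (72.9%) matched a named gene, and these held between 88.0% and 90.1% of the counts of a library. In 85.5% of the matched genes the gene entry lay within 5 counts of the sum of its transcripts in every library. Gene coordinates came from the RefSeq table of GRCh38.p14.

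Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (16130 genes), libraries were scaled by TMM, and 1 quasi-likelihood model (glmQLFit and glmQLFTest) with a mean per protocol was fitted to all 10 libraries, which share 1 estimate of the spread. The common biological coefficient of variation was 0.550. Each pairwise contrast was tested two-sided, an F test compared all 3 protocols, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are given on the log2 scale as the first-named protocol minus the second, with their standard errors.

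A set of 34 gene lists was fixed before the data were examined, together with the groups, the tests and the alternatives. The lists covered sensory neuron identity, pan-neuronal genes, markers of nociceptors, low-threshold mechanoreceptors and proprioceptors, neurofilament and large-axon genes, voltage-gated sodium channels, sensory transduction channels, neuropeptides, anterior and posterior HOX genes, Schwann and satellite glia, neural crest, fibroblast and mesenchyme, skeletal muscle, melanocytes, epithelium, endothelium, central neural progenitors, spinal and central neurons, autonomic neurons, pluripotency, proliferation, the nerve injury response, the unfolded protein and integrated stress response, heat shock, hypoxia and glycolysis, cholesterol synthesis, BMP and TGF-beta targets, WNT targets, the NOTCH pathway, retinoic acid targets, activity and MAPK response genes, and mitochondrially encoded genes. Lists were tested with camera in limma 3.58.1 on log2 CPM (counts scaled to library size) with a prior count of 2 and an inter-gene correlation preset at 0.01, which compares the members with all other tested genes, and the 102 tests were adjusted together. The preset correlation is small, so each call was repeated with a correlation estimated from the data. The level of a list in a library is the mean log2 CPM of its tested members.

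The genes to be named were, per contrast, the 10 largest changes in each direction past the threshold without overlap between the groups' libraries and with a mean TPM of at least 5 in the higher group, together with any member of the lists. NTRK2, NTRK3 and AVIL were to be given in every library. Some list members and 1 further gene of that rule are not reported here. No gene passed the threshold, so the named genes are list members, and any other gene named was chosen after its values were seen and is marked as such.

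Transcript usage, the division of a gene's counts among its transcripts, was tested with diffSpliceDGE in edgeR on transcripts kept by filterByExpr in genes with several such transcripts (57239 transcripts of 11321 genes), with a Simes p per gene. Quantification uncertainty of the transcripts was not used, so these p-values may be too small. Principal components and distances between libraries were computed from log2 CPM, and the share of variance between protocols was compared with all 4200 assignments of the libraries to groups of these sizes.

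The gene test, the list test and the usage test were tested on simulated counts with the means, library sizes and dispersions of the real data. Among 50 genes changed at each fold size, for mechanoreceptor against nociceptor (15894 genes tested) the gene test called 0% of genes changed 2-fold, 30% of those changed 4-fold and 70% of those changed 8-fold. For proprioceptor against nociceptor (15897 genes) these shares were 2%, 32% and 74%, and for proprioceptor against mechanoreceptor (15910 genes) 0%, 24% and 58%. The list test called 100% of 40 lists shifted 2-fold and 0.625% of 160 unchanged lists for mechanoreceptor against nociceptor. The simulated genes were drawn independently of each other. These shares therefore do not hold for lists whose members move together, such as proliferation genes (estimated correlation 0.653). For mechanoreceptor against nociceptor (11321 genes) the usage test called 1% of 200 genes with 1 transcript changed 8-fold, and 95.5% when the counts were drawn with 0.1 of the real dispersion. It also called 0.171% of the unchanged genes at the real dispersion and 0.665% at 0.1 of it.

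Alternatives named at the outset were DESeq2 1.42.0 (Wald tests, and a likelihood ratio test for the 3 protocols), DESeq2 size factors, no filter and a stricter filter on low counts, an offset for transcript length, limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean TPM of at least 1, a test against a 1.5-fold change, fits with only the groups compared, the replicate number as a block, an estimated inter-gene correlation, and leaving out each library in turn. Alternatives added after seeing the data were the mesenchyme list level as a covariate, an estimated inter-gene correlation under this and each other list alternative, limma voom with library weights, exact permutation of list levels, and exact permutation of the protocol labels for the share of variance. Correlations, distances and figures were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.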

Results

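The study differentiated RUES2 human embryonic stem cells carrying an AVIL:tdTomato reporter, which marks sensory neurons, along 3 protocols and profiled the cultures by bulk RNA-seq at day 60 in vitro. There were 4 libraries of the nociceptor protocol (pain- and itch-sensing neurons), 3 of the mechanoreceptor protocol (low-threshold touch neurons) and 3 of the proprioceptor protocol (neurons that sense muscle stretch). Named genes received 44541262, 35059647, 31306941 and 27891888 counts in nociceptor libraries 1 to 4. They received 37769095, 37920073 and 32813444 in mechanoreceptor libraries 1 to 3 and 27891186, 31836242 and 37340100 in proprioceptor libraries 1 to 3. Between 12066 and 14160 genes reached a TPM of at least 1 in a library. Values after ± are standard deviations for TPM (n = 4 for the nociceptor protocol, n = 3 for each of the others) and standard errors for log2 fold changes.

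AVIL, the gene that carries the reporter, lies on chromosome 12 at 57797380 to 57818734 of GRCh38.p14 and was low in every library. Its TPM was 1.17, 1.61, 1.87 and 1.89 in nociceptor libraries 1 to 4, 2.21, 3.55 and 1.40 in mechanoreceptor libraries 1 to 3 and 1.30, 3.51 and 2.96 in proprioceptor libraries 1 to 3. NTRK2, the receptor of brain-derived neurotrophic factor, was at a TPM of 23.0, 15.8, 20.9 and 29.8 in the nociceptor libraries, 16.2, 12.9 and 14.8 in the mechanoreceptor libraries and 7.24, 16.6 and 73.6 in the proprioceptor libraries. NTRK3, the receptor of neurotrophin-3 that proprioceptors use, was at 8.21, 3.92, 7.96 and 10.7, at 3.09, 5.02 and 8.54 and at 4.17, 8.16 and 0.988 in the same order of protocols. The libraries of the 3 protocols overlapped for both receptors. Between mechanoreceptor and nociceptor libraries the log2 fold change was -0.36 ± 0.56 for NTRK2 (edgeR adjusted p = 0.863). Between proprioceptor and nociceptor libraries it was -0.46 ± 0.62 for NTRK3 (adjusted p = 0.809). Neither difference exceeded the spread between libraries.

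**Figure D1:**
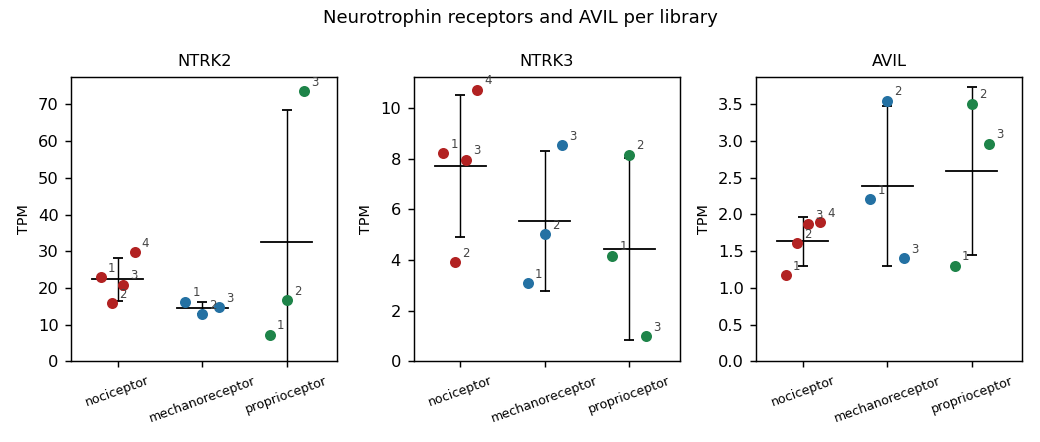
TPM of NTRK2, NTRK3 and AVIL in each of the 10 libraries, by protocol, with the replicate number beside each point. The line is the mean and the bar the SD (n = 4, 3 and 3), bars that reach below 0 end at the axis, the 3 protocols overlap for all 3 genes, and proprioceptor library 3 has the highest NTRK2 (73.6) and the lowest NTRK3 (0.988).

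Genes that somatosensory neurons express were present under all 3 protocols. Genes of autonomic neurons were also present in libraries of each protocol, so presence alone does not settle the type of neuron. ISL1, a transcription factor of sensory neurons, had a mean TPM of 200.1 ± 99.0 in nociceptor, 284 ± 122 in mechanoreceptor and 277 ± 121 in proprioceptor libraries. PRPH, which encodes the intermediate filament peripherin, had 636 ± 419, 724 ± 179 and 920.1 ± 130.4. POU4F1 (BRN3A), a regulator of sensory neuron identity, was lower, at 7.35 ± 7.56, 10.2 ± 5.40 and 8.45 ± 8.28. SCN9A, the sodium channel Nav1.7, was at 129 ± 90.7, 163 ± 28.0 and 145 ± 14.5. P2RX3, an ATP-gated channel of nociceptors, was at 179 ± 158, 365 ± 125 and 247 ± 215. The touch channel PIEZO2 was at 109.8 ± 155, 80.9 ± 31.2 and 111 ± 52.3. CALCA, TRPV1 and SCN11A, also genes of nociceptors, stayed low in every library. CALCA, the gene of calcitonin gene-related peptide, had at most 2.04 TPM, in mechanoreceptor library 2. TRPV1, the capsaicin receptor, had at most 4.97, in proprioceptor library 3, and SCN11A, the sodium channel Nav1.9, at most 2.35, in nociceptor library 4. PVALB, the calcium-binding protein parvalbumin of proprioceptors, had a mean TPM of 4.04 ± 2.44, 8.49 ± 1.65 and 9.11 ± 6.61. RUNX3, a transcription factor of the proprioceptor lineage, had 1.34 ± 0.743, 4.68 ± 1.79 and 3.01 ± 4.11.

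The libraries also carried RNA of cells other than neurons, in amounts that differed widely within each protocol. COL1A1, a collagen of fibroblasts, was at a TPM of 392, 506, 1984 and 17.0 in nociceptor libraries 1 to 4, 3.26, 2.88 and 366 in mechanoreceptor libraries 1 to 3 and 1.77, 536 and 7.81 in proprioceptor libraries 1 to 3. S100B, a gene of Schwann cells and other glia, was at 1638, 1098, 2295 and 238, at 10.8, 3.12 and 958 and at 85.7, 1214 and 34.6. The mean level of the fibroblast and mesenchyme list (mean log2 CPM, counts scaled to library size) was 5.45, 5.58, 5.54 and 2.68 in the nociceptor, 0.82, 1.18 and 4.89 in the mechanoreceptor and 1.71, 4.85 and 1.25 in the proprioceptor libraries. The level of the Schwann and satellite glia list was 6.62, 6.63, 7.04 and 5.01, then 2.69, 2.07 and 6.03, then 3.80, 6.26 and 3.23. Pan-neuronal genes were at 7.46, 7.47, 7.48 and 8.36, at 8.08, 8.38 and 8.17 and at 8.62, 8.10 and 8.59. The first principal component of the libraries held 52.8% of the variance, and all 3 protocols had libraries on both sides of 0 on it. Nociceptor libraries 1 to 3, mechanoreceptor library 3 and proprioceptor library 2 had scores above 0. The protocols accounted for 30.3% of the variance of all genes (exact permutation p = 0.194 over 4200 groupings, whose median share was 19.1%).

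**Figure D2:**
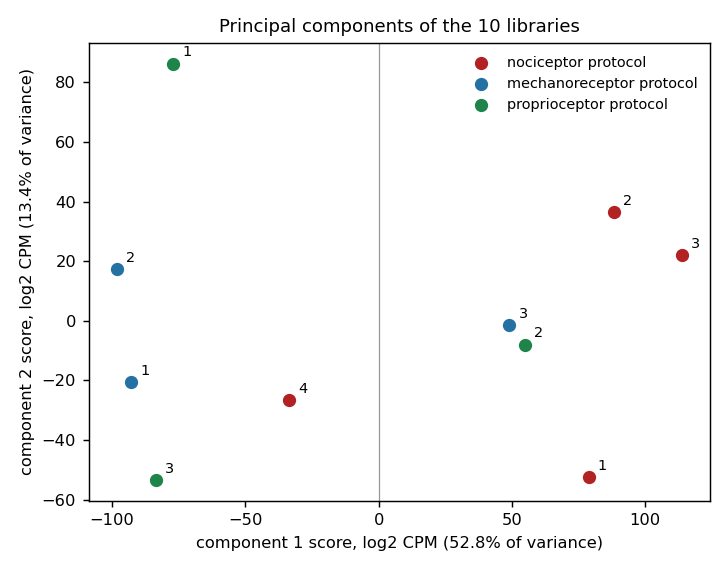
Scores of the 10 libraries on principal components 1 (52.8% of variance) and 2 (13.4%) of log2 CPM, coloured by protocol, with the replicate number beside each point. On component 1 nociceptor library 4 (-33.5) lies apart from nociceptor libraries 1 to 3 (78.7, 88.3 and 113.9), and mechanoreceptor library 3 (49.1) lies beside proprioceptor library 2 (54.8).

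**Figure D3:**
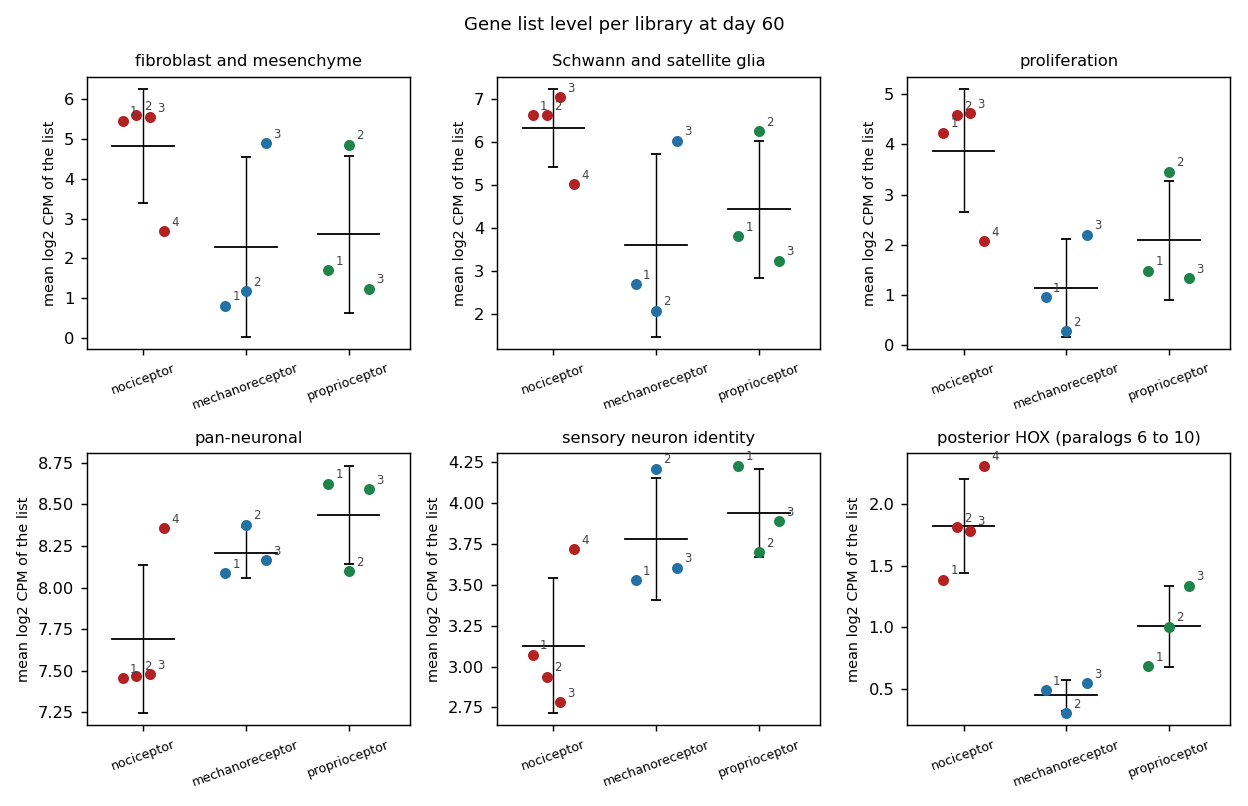
Level of 6 gene lists in each library, as the mean log2 CPM of the list's tested members, by protocol, with the replicate number beside each point. The line is the mean and the bar the SD (n = 4, 3 and 3), the vertical axes do not start at 0, and the posterior HOX list does not overlap between mechanoreceptor libraries (0.30 to 0.55) and nociceptor libraries (1.39 to 2.31).

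Mechanoreceptor cultures were compared with nociceptor cultures to ask what the touch-biased protocol changes against the pain-biased one. Genes of dividing cells, posterior HOX genes, and genes of glia, neural crest, mesenchyme and central neural progenitors were lower in the mechanoreceptor libraries, and neuronal lists were slightly higher. All 16 tested proliferation genes were lower, with a median log2 fold change of -3.05. TOP2A, a topoisomerase of dividing cells, had -4.29 ± 1.29 (mean TPM 10.1 ± 7.50 in nociceptor and 0.592 ± 0.438 in mechanoreceptor libraries), CCNA2, a cyclin, -3.48 ± 0.93, and CENPF, a centromere protein, -2.79 ± 0.71. The list passed (camera adjusted p = 4.68e-12, and adjusted p = 0.573 with an estimated correlation). On the log2(TPM + 1) scale its median was nearer 0 (-1.70, adjusted p = 9.04e-15). Of the proliferation genes, 12 passed adjusted over the list alone and 0 over all genes. The glia list had a median of -2.05, with 13 of 14 genes lower (SOX10, a glial transcription factor, -2.28 ± 1.67; adjusted p = 4.68e-05). The neural crest list had a median of -2.29, with 8 of 9 lower (PAX3 -2.29 ± 0.66, SNAI2 -2.73 ± 1.23; adjusted p = 0.000265). Fibroblast and mesenchyme genes had a median of -1.81, with 14 of 16 lower (COL1A1 -2.66 ± 2.15; adjusted p = 3.81e-05). Central neural progenitor genes had a median of -2.35, with all 4 lower (VIM -2.36 ± 1.08, NES -1.91 ± 0.85; adjusted p = 0.000425). With an estimated correlation each of these 4 lists had an adjusted p = 0.573. Adjusted over the list alone, 0 glia, 1 neural crest, 1 mesenchyme and 1 progenitor genes passed, and 0 of each over all genes.

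Posterior HOX genes, which set position along the trunk, were lower in mechanoreceptor libraries for 10 of 12 tested members (median -0.70, mean -1.55, camera adjusted p = 4.68e-05, and adjusted p = 0.454 with an estimated correlation). The list level was 1.39, 1.81, 1.79 and 2.31 in the nociceptor libraries and 0.49, 0.30 and 0.55 in the mechanoreceptor libraries, which did not overlap (exact permutation p = 0.0286, two-sided, the smallest that 4 against 3 libraries allow). The other passing lists had a larger exact permutation p. It was 0.0857 for proliferation, glia and central progenitor genes and 0.114 for neural crest and pan-neuronal genes. For mesenchyme and sodium channel genes it was 0.171, and for neurofilament genes 0.229. Pluripotency genes, which did not pass camera, also had an exact permutation p of 0.0286. The 3 members of the HOXC cluster on chromosome 12 were all lower. HOXC9 (54000161 to 54003337) had a log2 fold change of -4.55 ± 0.85 and a TPM of 4.47, 6.65, 7.07 and 8.73 in the nociceptor and 0.0629, 0.0915 and 0.784 in the mechanoreceptor libraries. HOXC8 (54008985 to 54012769) had -2.72 ± 0.81 and HOXC6 (54016888 to 54030823) -2.48 ± 0.79, and in the HOXA cluster HOXA7 had -1.94 ± 0.73. HOXA9 had 26, 21, 11 and 51 counts in the nociceptor and 0, 2 and 0 in the mechanoreceptor libraries. Of the HOXB cluster, HOXB7 had -0.55 ± 0.34 and HOXB9 -0.09 ± 0.60. Adjusted over the list alone 4 members passed, and 0 over all genes. Without mechanoreceptor library 2 the median was -1.26, adjusted p = 1.39e-06, on the log2(TPM + 1) scale, which compresses low genes, -0.46, adjusted p = 1.56e-05, and with the mesenchyme level as a covariate -1.36, adjusted p = 5.83e-11, and adjusted p = 0.165 with an estimated correlation as well.

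Neuronal lists were higher by less than 2-fold. Pan-neuronal genes had a median of 0.44, with 14 of 15 higher (adjusted p = 0.00840, and adjusted p = 0.573 with an estimated correlation). Neurofilament and large-axon genes had 0.46, with all 14 higher (NEFM, the medium neurofilament, 0.81 ± 0.57; adjusted p = 0.00323, and adjusted p = 0.613 with an estimated correlation). Voltage-gated sodium channels had 0.44, with 10 of 11 higher (SCN4B, a beta subunit, 1.52 ± 0.53; adjusted p = 0.0144, and adjusted p = 0.573 with an estimated correlation). No member of these passed adjusted over the list alone (0 of each) or over all genes. Sensory neuron identity genes had 0.37, with 12 of 15 higher, and did not pass (camera adjusted p = 0.0726, and adjusted p = 0.573 with an estimated correlation). Beside these lists, mesenchyme genes had a median of -1.81 and glia genes -2.05. With the mesenchyme level as a covariate, an alternative added after seeing the data, the pan-neuronal (0.03, adjusted p = 0.475), neurofilament (0.15, adjusted p = 0.330), sodium channel (0.41, adjusted p = 0.106) and neural crest (-0.40, adjusted p = 0.0976) lists no longer passed. The proliferation (-1.48, adjusted p = 1.16e-12), glia (-0.66, adjusted p = 0.00808) and central progenitor lists (-0.74, adjusted p = 0.00295) still passed with it at the preset correlation, but not at an estimated one (adjusted p = 0.400, 0.420 and 0.391). The sodium channel list was also lost without nociceptor library 2 (0.27, adjusted p = 0.0531), nociceptor library 3 (0.30, adjusted p = 0.0549) or mechanoreceptor library 3 (0.37, adjusted p = 0.0672). On the log2(TPM + 1) scale it was lost by its p alone (0.61, adjusted p = 0.0977), with a median farther from 0. Without mechanoreceptor library 3 the glia median was -4.79, the mesenchyme median -4.58, the neural crest median -4.13 and the progenitor median -4.26. Without nociceptor library 4 the pan-neuronal median was 0.73, the neurofilament median 0.97 and the sodium channel median 0.90. The pan-neuronal median was 0.29 without nociceptor library 1 and 0.27 without mechanoreceptor library 2. The neurofilament median was 0.30 and 0.26 without nociceptor libraries 2 and 3.

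The marker lists of the target neurons did not separate these protocols with the main design. Low-threshold mechanoreceptor markers had a median of 0.05 and a mean of -0.47, with 9 of 18 higher (adjusted p = 0.791, and adjusted p = 0.915 with an estimated correlation). With the mesenchyme level as a covariate they passed in the other direction (-0.64, adjusted p = 0.00808), but not at an estimated correlation (adjusted p = 0.487). SHOX2, a transcription factor of touch neurons, had 1.31 ± 0.79 and the receptor RET 0.55 ± 0.44. CALB1, the calcium-binding protein calbindin, had -4.53 ± 1.14 and MAF, a transcription factor of touch neurons, -1.56 ± 0.41, and these were the 2 members past the threshold adjusted over the list alone (0 over all genes). Nociceptor markers had a median of 0.35, with 12 of 20 higher (adjusted p = 0.381, and adjusted p = 0.613 with an estimated correlation, 0 adjusted over the list alone and 0 over all genes). RUNX1, a transcription factor of nociceptors, had -1.39 ± 0.47 and SST, the neuropeptide somatostatin, 2.62 ± 1.04. Proprioceptor markers had a median of -0.62, with 10 of 17 lower (adjusted p = 0.757, and adjusted p = 0.912 with an estimated correlation, 0 adjusted over the list alone and 0 over all genes). The lowest was SPP1, the secreted protein osteopontin, at -3.85 ± 1.17.

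In tests of single genes, edgeR called 0 of 16130 genes between mechanoreceptor and nociceptor libraries (smallest adjusted p = 0.598), with 1320 at an unadjusted p under 0.05. DESeq2 called 130 genes (16 higher, 114 lower). By limma voom with library weights, added after seeing the data, 4362 were called (2038 higher, 2324 lower), and by limma on log2(TPM + 1) 0. The library weights were 0.384, 3.77, 1.37 and 0.412 in nociceptor libraries 1 to 4 and 1.16, 3.22 and 0.882 in mechanoreceptor libraries 1 to 3. Library 2 of each protocol thus counted most. Of the list members, DESeq2 called 9 of 16 proliferation genes (TOP2A adjusted p = 0.00323, CCNA2 0.00320), HOXC9 (7.22e-07), HOXC8 (0.0332) and HOXC6 (0.0449). It called PRRX1, a transcription factor of mesenchyme (1.26e-06), which had 155, 178, 103 and 52 counts in nociceptor and 6, 0 and 1 in mechanoreceptor libraries. It also called CALB1 (0.000291), MAF (0.0333), SPP1 (0.00760), FABP7 (0.00991), PAX3 (0.0463), POU4F2 (0.0498), DPPA4 (0.00175) and L1TD1 (0.00991). All of these were lower in mechanoreceptor libraries. The count at an unadjusted p under 0.05 was 2580 without nociceptor library 4, 2435 without mechanoreceptor library 3, 765 without nociceptor library 2, and 804 without nociceptor library 3. It was 613 without mechanoreceptor library 1 and 486 without mechanoreceptor library 2.

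Proprioceptor cultures were compared with nociceptor cultures in the same way. Pan-neuronal, neurofilament and sensory identity genes were higher in the proprioceptor libraries, and genes of dividing cells, glia, neural crest, mesenchyme and central progenitors lower. All 15 pan-neuronal genes were higher (median 0.63, adjusted p = 4.68e-05, and adjusted p = 0.573 with an estimated correlation). Among them were STMN2, a tubulin-binding protein of growing axons (1.10 ± 0.48, mean TPM 2549 ± 1162 in nociceptor and 4806 ± 1668 in proprioceptor libraries) and ELAVL4, a neuronal RNA-binding protein (1.27 ± 0.54). Sensory neuron identity genes had a median of 0.75, with 12 of 15 higher (ISL2 1.85 ± 0.95, TLX3 1.21 ± 0.62; adjusted p = 0.00341, and adjusted p = 0.573 with an estimated correlation). Neurofilament and large-axon genes had 0.62, with 13 of 14 higher (NEFL, the light neurofilament, 0.96 ± 0.47; adjusted p = 0.00212, and adjusted p = 0.586 with an estimated correlation). Adjusted over the list alone, 0 pan-neuronal, 0 sensory identity and 0 neurofilament genes passed, and 0 over all genes. Beside these, the mesenchyme list was lower in 15 of 16 genes (median -1.80, adjusted p = 4.68e-05, and adjusted p = 0.573 with an estimated correlation). Voltage-gated sodium channels had 0.45, with 9 of 11 higher, and did not pass (camera adjusted p = 0.0523, and adjusted p = 0.613 with an estimated correlation).

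All 16 proliferation genes were lower in proprioceptor libraries (median -1.75, adjusted p = 2.39e-07; CENPF -1.59 ± 0.67). So were all 9 neural crest genes (median -1.75, adjusted p = 0.000188) and all 4 central progenitor genes (median -2.08, adjusted p = 0.00323; SOX2 -2.23 ± 1.63). Glia genes were lower in 13 of 14 (median -1.68, adjusted p = 0.000447; S100B -1.70 ± 1.66). Spinal and central neuron genes were lower in 9 of 9 (median -1.10, adjusted p = 0.0248, and adjusted p = 0.586 with an estimated correlation; DLX1 -2.27 ± 1.62). BMP and TGF-beta targets were lower in 11 of 12 (median -0.87, adjusted p = 0.0175; ID3 -3.55 ± 1.83). Activity and MAPK response genes were lower in 13 of 17 (median -0.56, adjusted p = 0.0106; DUSP6 -1.81 ± 0.82). With an estimated correlation the adjusted p was 0.573 for all of these but the spinal and central neuron list. In each of these 7 lists 0 members passed over all genes and 0 adjusted over the list alone. Posterior HOX genes were lower in 7 of 12 (median -0.12, mean -0.94, adjusted p = 0.0300, and adjusted p = 0.573 with an estimated correlation). HOXC9 had -2.01 ± 0.74 and HOXA7 -2.01 ± 0.74, whereas HOXB9 had 0.87 ± 0.60. HOXA9, with 0, 1 and 0 counts in the proprioceptor libraries, was the 1 member past the threshold adjusted over the list alone (0 over all genes).

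Several of these calls were lost without single libraries or with the mesenchyme level as a covariate. Some were lost by their p alone, with a median farther from 0 than with all libraries. Without proprioceptor library 3 the neurofilament (0.27, adjusted p = 0.0827), glia (-1.16, adjusted p = 0.0510), spinal and central neuron (-1.44, adjusted p = 0.295), BMP and TGF-beta (-0.61, adjusted p = 0.289) and MAPK lists (-0.68, adjusted p = 0.162) were lost. The BMP and TGF-beta list (-0.87 with all libraries) was also lost without nociceptor library 1 (-0.90, adjusted p = 0.106) or 2 (-0.49, adjusted p = 0.0733). The spinal and central neuron list (-1.10 with all libraries) was also lost without nociceptor library 1 (-0.85, adjusted p = 0.0544) or 2 (-0.85, adjusted p = 0.0531), mechanoreceptor library 1 (-0.86, adjusted p = 0.0511) or proprioceptor library 1 (-0.76, adjusted p = 0.180). It was also lost on the log2(TPM + 1) scale (-1.33, adjusted p = 0.0532), with a median farther from 0. The posterior HOX list was lost without nociceptor library 4 (-0.18, adjusted p = 0.186) or proprioceptor library 2 (-1.43, adjusted p = 0.106) and on the log2(TPM + 1) scale (-0.20, adjusted p = 0.114). Its median ranged from -1.43 to -0.01 as single libraries were left out. Without proprioceptor library 2 the medians were -3.14 for glia, -3.85 for neural crest, -4.33 for mesenchyme, -3.14 for central progenitors, -2.88 for proliferation and -0.95 for MAPK genes. Without nociceptor library 3 the mesenchyme median was -1.16. Without nociceptor library 4 the pan-neuronal median was 1.17 and the neurofilament median 1.00. On the log2(TPM + 1) scale the neurofilament median was 0.37 (adjusted p = 0.00194). Without proprioceptor library 1 or 3 the sensory identity median was 0.46 or 0.45. With the mesenchyme level as a covariate, the pan-neuronal (0.41, adjusted p = 0.00140), proliferation (-0.56, adjusted p = 0.000384) and posterior HOX lists (-0.35, adjusted p = 1.24e-05) passed at the preset correlation, but not at an estimated one (adjusted p = 0.420, 0.487 and 0.391). The other 9 lists did not pass. The MAPK list turned from -0.56 to 0.21, adjusted p = 0.526. Medians moved toward 0, to -0.09 for glia, -0.10 for mesenchyme (whose level was the covariate), -0.50 for neural crest, -0.43 for central progenitors, -0.33 for spinal and central neurons, -0.30 for BMP and TGF-beta targets, 0.24 for neurofilament genes and 0.42 for sensory identity (adjusted p from 0.0685 to 0.876).

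None of the 3 target marker lists separated the proprioceptor from the nociceptor libraries. Proprioceptor markers had a median of -0.35, with 8 of 17 higher (adjusted p = 0.855, and adjusted p = 0.915 with an estimated correlation; PVALB 1.60 ± 0.78, ETV1, a transcription factor of proprioceptors, -0.35 ± 0.59, SPP1 -3.34 ± 1.14). Nociceptor markers had 0.37, with 12 of 20 higher (adjusted p = 0.543, and adjusted p = 0.728 with an estimated correlation). Low-threshold mechanoreceptor markers had 0.26, with 12 of 18 higher (adjusted p = 0.290, and adjusted p = 0.785 with an estimated correlation). Adjusted over the list alone 0, 2 and 1 members passed, and 0 over all genes. The nociceptor markers were SST (4.29 ± 1.10, TPM 75.2, 629.6, 457 and 597 in nociceptor and 13358, 1389.5 and 1884 in proprioceptor libraries) and RUNX1 (-1.70 ± 0.47), and the touch marker was CALB1 (-4.45 ± 1.14). Without nociceptor library 4 the low-threshold mechanoreceptor markers passed (1.08, adjusted p = 0.0426), but not with an estimated correlation (adjusted p = 0.5155). In tests of single genes edgeR called 0 genes (smallest adjusted p = 0.665), with 998 at an unadjusted p under 0.05. DESeq2 called 31 (12 higher, 19 lower), and limma voom with library weights and limma on log2(TPM + 1) each called 0. The list members called by DESeq2 were CALB1 (adjusted p = 0.00245), PENK, the opioid peptide precursor proenkephalin (0.0206), PRRX1 (0.0370), HOXA9 (0.0441) and DPPA4 (0.0476). All were lower in proprioceptor libraries. The count at an unadjusted p under 0.05 was 2704 without proprioceptor library 2, 2458 without nociceptor library 4, 614, 533 and 490 without nociceptor libraries 1, 2 and 3, and 600 without proprioceptor library 3.

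Proprioceptor cultures were last compared with mechanoreceptor cultures, the protocols for the 2 kinds of large-fibre neuron. Mitochondrially encoded genes, proliferation genes, posterior HOX genes, skeletal muscle genes and low-threshold mechanoreceptor markers were higher in the proprioceptor libraries, and genes of the unfolded protein and integrated stress response lower. All 13 mitochondrial genes were higher (median 0.80, adjusted p = 4.68e-05, and adjusted p = 0.586 with an estimated correlation; MT-CO2, a subunit of cytochrome c oxidase, 0.92 ± 0.63). Proliferation genes were higher in 15 of 16 (median 1.26, adjusted p = 0.000568, and adjusted p = 0.613 with an estimated correlation). Posterior HOX genes were higher in 8 of 12 (median 0.78, adjusted p = 0.00213, and adjusted p = 0.573 with an estimated correlation; HOXC9 2.54 ± 0.81, HOXB7 0.79 ± 0.36). Muscle genes were higher in all 5 that were tested, of 11 on the list (median 0.52, adjusted p = 0.0116, and adjusted p = 0.573 with an estimated correlation; TNNT1, a troponin, 0.82 ± 0.81). Low-threshold mechanoreceptor markers, the markers of the other protocol's target, were higher in 15 of 18 (median 0.36, adjusted p = 0.0212, and adjusted p = 0.573 with an estimated correlation; TAFA1 1.76 ± 1.15, NTRK2 1.20 ± 0.61, NECAB2 0.92 ± 0.74). Stress response genes were lower in 13 of 14 (median -0.33, adjusted p = 0.00222, and adjusted p = 0.573 with an estimated correlation; TRIB3, a pseudokinase of the stress response, -0.83 ± 0.47). In each of these 6 lists 0 members passed over all genes and 0 adjusted over the list alone. Proprioceptor markers had a median of 0.15 (adjusted p = 0.855, and adjusted p = 0.915 with an estimated correlation) and nociceptor markers 0.03 (adjusted p = 0.856, and adjusted p = 0.915 with an estimated correlation). Mesenchyme genes had a median of 0.04 and glia genes 0.30 (adjusted p = 0.340 and 0.173).

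Each of these 6 calls was lost when some library was left out. The touch markers were lost without mechanoreceptor library 3 (0.53, adjusted p = 0.320), proprioceptor library 2 (0.65, adjusted p = 0.0573) or proprioceptor library 3 (0.02, adjusted p = 0.634). The mitochondrial genes were lost without mechanoreceptor library 1 (0.46, adjusted p = 0.143) or proprioceptor library 1 (0.10, adjusted p = 0.300) and the posterior HOX genes without proprioceptor library 3 (0.19, adjusted p = 0.104). The proliferation genes were lost without mechanoreceptor library 2 (0.89, adjusted p = 0.0840) and turned without proprioceptor library 2 (-0.12, adjusted p = 0.422), with a median of 2.24 without mechanoreceptor library 3. The muscle genes were lost without mechanoreceptor library 1 (0.43, adjusted p = 0.0581) or 3 (0.53, adjusted p = 0.159) or proprioceptor library 1 (0.28, adjusted p = 0.168) or 3 (0.82, adjusted p = 0.0997). The stress response genes were lost without mechanoreceptor library 1 (-0.16, adjusted p = 0.0511), proprioceptor library 2 (-0.23, adjusted p = 0.0689) or proprioceptor library 3 (-0.14, adjusted p = 0.242). The touch marker median was 0.61, 0.62 and 0.60 without mechanoreceptor libraries 1 and 2 and proprioceptor library 1. Without proprioceptor library 1 the posterior HOX median was 0.49 and the stress response median -0.59. On the log2(TPM + 1) scale the medians were 0.02 for touch markers, 0.43 for posterior HOX, 0.13 for muscle and 0.44 for proliferation genes. They were -0.65 for stress response and 0.42 for mitochondrial genes, where the median of all genes was -0.22. With the mesenchyme level as a covariate all 6 lists passed (touch markers 0.58, proliferation 0.73), and with an estimated correlation as well 0 did. For single genes edgeR, DESeq2, limma voom with library weights and limma on log2(TPM + 1) each called 0. In edgeR 241 genes had an unadjusted p under 0.05 (smallest adjusted p = 1), with 117 without mechanoreceptor library 1, 714 without mechanoreceptor library 3 and 738 without proprioceptor library 2. POU4F2, a sensory transcription factor, had 3.46 ± 0.91. It was the 1 sensory identity gene past the threshold adjusted over the list alone (0 over all genes), in a list with a median of -0.04 (adjusted p = 0.390).

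**Figure D4:**
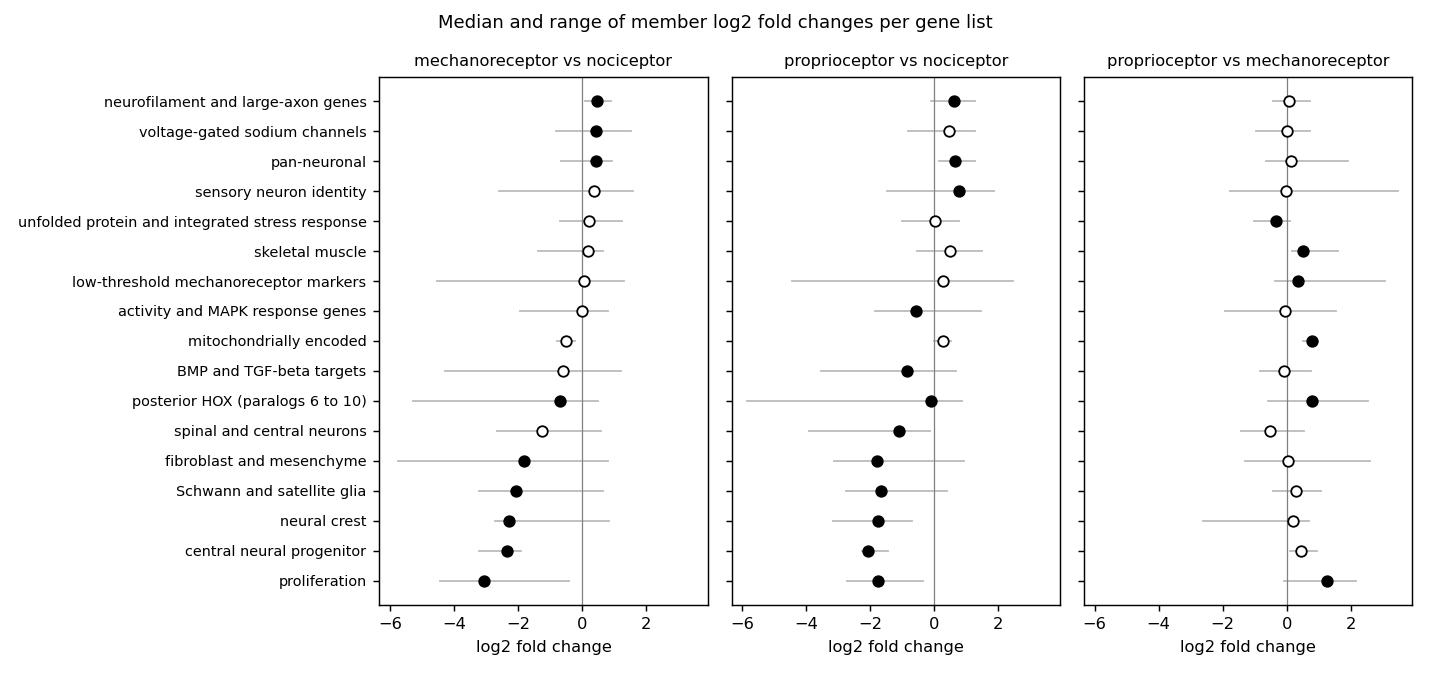
Median log2 fold change of the members of each gene list (point) and the range of its members (line) in the 3 comparisons, first-named protocol minus second, for the 17 lists that passed in at least 1 comparison. Filled points passed camera at an adjusted p of 0.05 over 102 tests with a preset correlation of 0.01, none passed with an estimated correlation, and proliferation is lowest at -3.05 in mechanoreceptor against nociceptor libraries.

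The remaining lists passed in no comparison with the main design. Their medians are given for mechanoreceptor against nociceptor, proprioceptor against nociceptor and proprioceptor against mechanoreceptor in that order. Sensory transduction channels had 0.35, 0.33 and 0.11 (adjusted p = 0.173, 0.286 and 0.713) and neuropeptides 0.48, 0.14 and -0.38 (adjusted p = 0.237, 0.869 and 0.0679). Anterior HOX genes had -0.13, 0.12 and 0.28 (adjusted p = 0.808, 0.874 and 0.858) and autonomic neuron genes -0.13, -0.48 and -0.13 (adjusted p = 0.180, 0.806 and 0.144). Melanocyte genes had 0.46, -1.50 and -0.83 (adjusted p = 0.855, 0.0973 and 0.0734) and epithelial genes -1.62, -1.33 and 0.43 (adjusted p = 0.0660, 0.286 and 0.194). Endothelial genes had -0.85, -1.52 and 0.64 (adjusted p = 0.381, 0.237 and 0.806) and pluripotency genes -0.62, -0.34 and 0.31 (adjusted p = 0.173, 0.216 and 0.649). The pluripotency level did not overlap between nociceptor (0.35 to 0.52) and mechanoreceptor libraries (-0.72 to -0.06; exact permutation p = 0.0286). In that comparison 2 pluripotency genes passed adjusted over the list alone, and 0 over all genes. Nerve injury genes had -0.40, -0.22 and 0.36 (adjusted p = 0.308, 0.796 and 0.290) and heat shock genes -0.03, 0.05 and 0.07 (adjusted p = 0.796, 0.855 and 0.463). Hypoxia and glycolysis genes had 0.05, 0.04 and 0.12 (adjusted p = 0.969, 0.855 and 0.839) and cholesterol synthesis genes -0.10, 0.08 and 0.24 (adjusted p = 0.889, 0.529 and 0.286). For signalling, WNT targets had -0.22, -0.04 and -0.27 (adjusted p = 0.874, 0.286 and 0.203) and NOTCH pathway genes 0.23, -0.23 and -0.28 (adjusted p = 0.872, 0.308 and 0.273). Retinoic acid targets had -0.24, -0.56 and -0.27 (adjusted p = 0.558, 0.314 and 0.757). The median had another sign than the mean or the test for touch markers, skeletal muscle, melanocyte, autonomic, hypoxia and NOTCH genes in the first comparison. It did so for neuropeptides, anterior HOX, autonomic, stress response and hypoxia genes in the second. In the third it did so for sensory identity, nociceptor, sodium channel, transduction channel, neural crest, endothelial, nerve injury and hypoxia genes. None of these tests passed with the main design.

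Some tests of lists that did not pass with the main design did so under an alternative, at the preset correlation of 0.01. These made 78 calls, of which 0 passed when the correlation was estimated under the same alternative (smallest adjusted p = 0.406), a repeat added after seeing the data. With the mesenchyme level as a covariate, an alternative added after seeing the data, 5 of 25 such tests passed for mechanoreceptor against nociceptor. These were autonomic neuron genes (median -0.13 without and 1.97 with the covariate, adjusted p = 1.45e-07, and adjusted p = 0.438 with an estimated correlation of 0.802), neuropeptides (0.69, adjusted p = 0.000508), mitochondrially encoded genes (-0.67, adjusted p = 0.00253), touch markers (-0.64, adjusted p = 0.00808) and cholesterol synthesis genes (-0.38, adjusted p = 0.0177). For proprioceptor against nociceptor 2 of 22 passed, the autonomic (-0.48 without and 1.29 with the covariate, adjusted p = 5.62e-05, and adjusted p = 0.509 with that estimated correlation) and stress response genes (-0.37, adjusted p = 0.00723). For proprioceptor against mechanoreceptor 3 of 28 passed, the glia (0.48, adjusted p = 0.0347), neuropeptide (-0.43, adjusted p = 0.0456) and autonomic genes (-0.17, adjusted p = 0.0471). With 1 library left out, 8, 6 and 12 such tests passed at least once in the 3 comparisons in the order above. The autonomic list then passed for mechanoreceptor against nociceptor without nociceptor library 2 (1.47, adjusted p = 0.000512) or 3 (0.08, adjusted p = 0.0445) or mechanoreceptor library 1 (0.36, adjusted p = 0.00529). For proprioceptor against nociceptor it passed without nociceptor library 2 (0.90, adjusted p = 0.0353) or proprioceptor library 3 (0.09, adjusted p = 0.0180). For proprioceptor against mechanoreceptor it passed without mechanoreceptor library 1 (-0.60, adjusted p = 0.00202) or proprioceptor library 1 (-0.96, adjusted p = 0.00768). With the replicate number as a block, which takes nociceptor library 4 out of the contrasts, 4, 3 and 1 passed. On the log2(TPM + 1) scale 4, 1 and 2 passed, and with DESeq2 size factors 0, 1 and 1.

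Across all 3 protocols the F test of edgeR called 0 genes (smallest adjusted p = 0.813), with 925 at an unadjusted p under 0.05. That count was 489, 471 and 2114 without nociceptor libraries 2, 3 and 4, 515, 503 and 1867 without mechanoreceptor libraries 1, 2 and 3, and 2037 without proprioceptor library 2. DESeq2 called 79 and limma voom with library weights 2797. The division of counts among transcripts was called different by diffSpliceDGE for 25 genes between mechanoreceptor and nociceptor libraries and for 18 between proprioceptor and nociceptor libraries out of 11321 tested. Between proprioceptor and mechanoreceptor libraries it called 0, where 707 genes had an unadjusted p under 0.05, the smallest adjusted p was 0.0642 and no other tool was run. In 23 of the 25 genes and 16 of the 18 the transcript with the largest difference was listed at a TPM of 0 in at least 1 library. List members among them were HSPA8, a heat shock protein, in the first comparison (lead transcript usage -5.10 on the log2 scale, adjusted p = 0.0126). In the second they were SPRY4, an inhibitor of MAPK signalling (-6.91, adjusted p = 0.0218), and THY1, a surface protein of axons and fibroblasts (-5.01, adjusted p = 0.0360). The lead transcript of HSPA8 had a TPM of 296, 5.78e-06, 0 and 40.9 in nociceptor and 1.28e-08, 0 and 2.24 in mechanoreceptor libraries. In nociceptor against proprioceptor libraries that of THY1 had 0, 11.5, 19.4 and 68.0 against 1.40e-07, 0.00128 and 0.397. That of SPRY4 had 1.72, 1.68, 0.938 and 5.47 against 0, 0 and 0. With single libraries left out the numbers of genes called for usage ran from 2 (without mechanoreceptor library 2) to 49 (without proprioceptor library 1) in the first comparison. They ran from 4 (without mechanoreceptor library 2) to 44 (without nociceptor library 4) in the second and from 0 to 3 in the third. On simulated counts for mechanoreceptor against nociceptor the test called 0.171% of unchanged genes, so many of the usage calls may be false.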

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

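In this part, the tests of transcript usage and of DESeq2 calls on other splits of the libraries were chosen before their results were seen, and all other tests were chosen only after the result was seen. The search for libraries far from the others of their group covered 144 values in the nociceptor protocol, whose 4 libraries are enough for it. Chance marks about 1 in 20 such groups if the values are normally distributed. Most of the values marked were TPM without a log transform, for which this share may be too low. The search found 21, of which 20 were in nociceptor library 4, where values are correlated and not independent of each other. In list levels, nociceptor library 4 was highest in pan-neuronal genes (8.36, next 7.48) and lowest in fibroblast and mesenchyme (2.68, next 5.45) and proliferation genes (2.07, next 4.23). Its TPM was far above the other nociceptor libraries for the pan-neuronal gene RBFOX3 (51.2), for the sensory neuron genes PRPH (1259.7), ISL2 (59.6), SCN11A (2.35), TRPM8 (28.7), PIEZO2 (341) and RET (98.0), for the neurofilament gene NEFM (2651) and the sodium channel subunit SCN4B (2.97), for HOXA9 (1.97), HOXC8 (5.66) and HOXB9 (36.5), and for ETV4 (96.3), CHAC1 (77.8), ATF5 (19.8), MT-ND4 (15107) and TTN (12.6). TRPA1, an irritant receptor, was far above the others in nociceptor library 1 (81.7, next 5.32). The entry with no gene name took 8.80% of the TPM in nociceptor library 1, and 2.81% in the library with the lowest share.

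Glial and mesenchymal RNA parted libraries of the same protocol. The SD over the 10 libraries of the difference between both list levels was 0.244 of the SD of the mesenchyme level, so the lists moved together. A differing share of glial and mesenchymal cells may underlie this. The value cannot decide it, because the pattern was picked for both lists parting the same libraries. All 3 protocols had libraries on both sides of 0 on the first principal component, so no single swap of 2 labels can clear all of them, and a swap was not excluded. Of 33 swaps of 2 library labels between protocols, 2 cleared both protocols they touch, those of nociceptor library 4 with mechanoreceptor library 3 or with proprioceptor library 2. No biological explanation was tested, nor where a differing share would come from.

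Posterior HOX genes were lower in mechanoreceptor than in nociceptor libraries. With the mesenchyme level as a covariate the median was -1.36, farther from 0 than the -0.70 without it, which argues against mesenchymal RNA as the whole cause. With an estimated correlation the list did not pass with the covariate (adjusted p = 0.165) or without it (0.454). The exact permutation p of the list level was 0.537 after adjustment over all list tests, a value that 4 against 3 libraries could bring under 0.05 only if most lists had the smallest p, so chance in 1 of many lists may remain. A difference in axial position set by the protocols is an open biological hypothesis, which was not tested.

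Mechanoreceptor library 3 and proprioceptor library 2 were the closest of all pairs of libraries. The chi-square between their counts was 36.9 per degree of freedom, far above sampling noise, which argues against 1 library entered under both names, although the lowest value within a protocol was 141.7. Leaving the partner out, the mean distance to the other 2 libraries of the partner's protocol minus that to the 2 others of the own protocol was 0.0632 for mechanoreceptor library 3 and -0.0018 for proprioceptor library 2. With the partner among 3 libraries the differences were -0.219 and -0.286, but that includes the pair chosen for being closest. Whether either may carry a wrong label stays open.

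The counts of calls were compared with those of other splits of the libraries into groups of the same sizes. For mechanoreceptor against nociceptor, 6 of 35 splits gave as many genes at an unadjusted p under 0.05 as the 1320 observed (highest other 3530), 15 gave as many lists as the 9 observed (highest other 15), 16 as many usage calls as the 25 observed (highest other 111) and 3 as many DESeq2 calls as the 130 observed (highest other 2100). For proprioceptor against nociceptor these were 13 of 35 splits for 998 genes (highest other 4200), 4 for 13 lists when adjusted within the comparison (highest other 18), 25 for 18 usage calls (highest other 147) and 8 for 31 DESeq2 calls (highest other 2369). Over the 3 protocols, 30 of 100 splits gave as many as 925 genes (highest other 2817). Chance could not be excluded for any of these. Proprioceptor against mechanoreceptor has 10 splits, too few for a share under 0.05, with 6 splits for 241 genes (highest other 2623), 4 for 6 lists (highest other 14) and 10 for 0 usage calls (highest other 65). Splits with several times the observed calls point to a structure of the samples. The highest for genes joined nociceptor library 4 with mechanoreceptor libraries 1 and 2, or with proprioceptor libraries 1 and 3.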

How the results depend on the processing

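The mesenchyme covariate, an estimated correlation under it and under each other list alternative, the library weights and the exact permutation tests were alternatives added after seeing the data, and the others were planned. The edgeR counts of 0 genes stayed at 0 under each other edgeR and limma alternative and with each library left out, except that DESeq2 called 130 genes for mechanoreceptor against nociceptor, 31 for proprioceptor against nociceptor and 79 over the 3 protocols, and limma voom with library weights called 4362 and 2797 in the first and the last of these. The library weights were highest for nociceptor library 2 (3.77) and mechanoreceptor library 2 (3.22). The cause of these calls was not tested. On the log2(TPM + 1) scale the median of all genes was 0.15 for mechanoreceptor against nociceptor and -0.22 for proprioceptor against mechanoreceptor. The nociceptor marker median was 0.35 in the first of these and -0.15 in the second.

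With the mesenchyme level as a covariate, the median of low-threshold mechanoreceptor markers was -0.64 for mechanoreceptor against nociceptor (adjusted p = 0.00808) and 0.044 for proprioceptor against nociceptor, and that of proprioceptor markers -0.22 and 0.023. The mesenchyme list itself turned to 0.003876 in the first comparison, by construction, since its level was the covariate. With an estimated correlation the touch markers (0.36) no longer passed for proprioceptor against mechanoreceptor, by the wider spread that the correlation gives, and neither did they with the covariate as well (0.58). A stricter filter on low counts gave 2 usage calls for proprioceptor against mechanoreceptor, and the cause was not tested.

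With 1 library left out, the median for mechanoreceptor against nociceptor ran from -0.31 to 0.90 for touch markers and from -0.94 to -0.28 for proprioceptor markers. For proprioceptor against nociceptor it ran from -0.46 to 1.08 for touch markers and from -0.44 to 0.28 for proprioceptor markers. For proprioceptor against mechanoreceptor it ran from -0.19 to 0.77 for nociceptor markers, from 0.016 to 0.65 for touch markers and from -0.22 to 0.45 for proprioceptor markers. Usage calls ran from 2 to 49, from 4 to 44 and from 0 to 3 in the 3 comparisons. The cause was not tested beyond there being fewer libraries. Of values for single genes and other lists, 6946 kept their direction and side of the threshold or stayed within the spread, 902 moved and 272 crossed the threshold or turned.

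The replicate numbers were not taken to pair the libraries, by a rule set before that every same-number pair correlate over 0.1. The library names run in order of replicate number across the protocols. The correlations therefore cannot tell whether libraries of 1 number were handled together. Of 9 same-number pairs 4 had a correlation over 0.1 (range -0.63 to 0.49), and 0 libraries were closest to their own number. Nociceptor library 4 is the only library with its number, so with the replicate number as a block it no longer contributed to the contrasts. With this block, the touch marker median was 0.93 for mechanoreceptor against nociceptor. Usage calls were 9, 11 and 1 in the 3 comparisons, and edgeR called 0 genes in each. Medians that moved over 1.5 times and still passed were 0.75 for pan-neuronal, 1.00 for neurofilament, 0.96 for sodium channel, -3.15 for glia and -2.94 for mesenchyme genes in the first comparison, and 1.13 for sensory identity and 1.10 for pan-neuronal genes in the second. The posterior HOX (-0.27, adjusted p = 0.147) and spinal and central neuron lists (-0.56, adjusted p = 0.0516) were lost for proprioceptor against nociceptor. Leaving out nociceptor library 4 alone gave medians of 0.73 for pan-neuronal, 0.97 for neurofilament and 0.90 for sodium channel genes in the first comparison. Without it the glia and mesenchyme medians of the first comparison and the sensory identity median of the second did not move over 1.5 times. The sensory identity median of the first comparison moved from 0.37 to 0.91 and passed camera (adjusted p = 0.0223), but not with an estimated correlation (adjusted p = 0.484). Apart from the loss of nociceptor library 4, the cause was not tested. The depth of 27891186 to 44541262 counts per library leaves the few counts of genes such as HOXA9 as the limit of depth, and the spread between libraries as the larger error elsewhere.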

Other observations

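The tests of the relations of autonomic genes with POU4F1 and with the sensory identity list in this part were chosen only after the values were seen. Genes of autonomic neurons varied more between libraries of a protocol than between protocols. TH, the rate-limiting enzyme of catecholamine synthesis, was at a TPM of 14.2, 248, 174 and 5.82 in nociceptor libraries 1 to 4, 70.9, 273 and 534 in mechanoreceptor libraries 1 to 3 and 378, 312 and 13.0 in proprioceptor libraries 1 to 3. DBH, which makes noradrenaline, was at 1.56, 90.1, 40.8 and 0.0933, at 5.95, 38.9 and 64.9 and at 7.26, 7.30 and 0.182. The level of the autonomic list (mean log2 CPM) was -0.17, 4.69, 3.00 and -2.33, then 1.19, 3.20 and 3.82, then 3.32, 2.81 and -1.36.

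Peptides also differed within protocols. SST, the gene of somatostatin, was at a TPM of 75.2, 629.6, 457 and 597 in the nociceptor, 2313, 5341 and 1507 in the mechanoreceptor and 13358, 1389.5 and 1884 in the proprioceptor libraries. TAC1, the substance P precursor, was at 1693, 1136, 381 and 215, at 39.8, 274 and 1129 and at 230.3, 738 and 53.6. NTS, the neurotensin precursor, was at 236, 66.7, 445 and 402, at 81.2, 76.5 and 606 and at 498, 281 and 7.23. Posterior HOX genes differed by cluster, with median log2 fold changes for mechanoreceptor against nociceptor of -2.72 over 3 HOXC genes and -0.50 over 4 HOXB genes, and for proprioceptor against nociceptor of -1.89 and 0.34, a difference between clusters that was not tested.

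A hypothesis is that sensory and autonomic neurons take opposite shares of the neurons in a culture. Across the 10 libraries the autonomic list level and log2(TPM + 1) of POU4F1 had Pearson r = -0.798 (permutation p = 0.00684, adjusted p = 0.0137) and Spearman rho = -0.685 (permutation p = 0.0351, adjusted p = 0.0703). Without nociceptor library 3 and proprioceptor library 3, the farthest from the median of POU4F1, r was -0.790. POU4F1 is 1 gene, chosen after its values were seen. The level of the sensory neuron identity list, which holds POU4F1 and was fixed before, had r = -0.122 with the autonomic level (permutation p = 0.728, adjusted p = 0.728) and rho = -0.127 (permutation p = 0.732, adjusted p = 0.732). Without nociceptor libraries 2 and 3, the farthest from the median of that list, r was 0.347. These were the 2 relations computed, each with 100000 permutations, two-sided, and adjusted over both. They leave the hypothesis undecided, and a cell-level measurement was not analysed here.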
